A study of Mus musculus with 6 samples.

How the data were processed

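Single-cell RNA sequencing libraries of mouse skin were analysed, 2 of unwounded skin and 2 of wound edge from Hdac5fl/fl mice, and 2 of wound edge from K14cre;Hdac5fl/fl mice, in which Cre recombinase is driven by the keratin 14 promoter of basal keratinocytes. The wound edge came from excisional wounds held open with a splint, per the labels' design text. The libraries were droplet libraries of the 3' end of polyadenylated RNA with cell barcodes and unique molecular identifiers (UMIs), made with the Chromium Single cell 3' v3 chemistry per the labels' protocols. The labels number biological replicates and do not say how many animals went into each library, or whether replicates were separate animals. The p-values below therefore measure the spread between libraries.

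The deposited files hold UMI counts per gene and barcode that the authors had not normalized, as whole numbers. The matrices were made with Cell Ranger version 7.0.1, per the file headers, and Cell Ranger, STAR and the mm10 build are named per the submitters' processing notes. Which annotation and which filter on barcodes the authors used is not given in the sources used here. Of the 32285 feature identifiers, 32158 (99.6%) were found in GENCODE vM21 (GRCm38, the assembly of mm10), from which gene positions were taken, and the 164 named genes that were looked up all had one. The libraries held 9888 and 9485 barcodes in unwounded skin, 11555 and 12575 in control wound edge and 11556 and 9752 in cKO wound edge, and none had fewer than 500 UMIs.

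Barcodes with at least 500 UMIs, at least 300 genes and under 20% mitochondrial UMIs were kept, 63114 cells in all. Doublets were scored with Scrublet in scanpy 1.11.5 at an expected rate of 8%. The automatic threshold was used where it marked at least 0.5% of cells, and the 8% of barcodes with the highest scores were taken otherwise. This removed 7.87% and 1.27% of cells in unwounded skin, 4.00% and 4.32% in control wound edge, and 7.65% and 3.97% in cKO wound edge, which left 60019. The first unwounded and the first cKO library took the fallback rule. Cells were clustered on 3000 variable genes and 40 principal components with a shared nearest neighbour graph over 20 neighbours and the Leiden algorithm (leidenalg 0.10.2) at a resolution of 0.6, without batch integration. Clusters with high scores for more than 1 cell family were split again, which gave 58 clusters. A cluster was named from fixed markers of 22 classes where its mean marker score was at least 1, at least 3 markers were seen in at least 10% of its cells, and its 10 leading genes did not favour another class. A cluster also stayed unnamed where at least 90% of its cells came from 1 library or at least 50% were called doublets. The same held where its UMIs were low and no marker of its class was among its leading genes. A cluster led by Acp5 and Ctsk was left unnamed because no class holds these genes. Of the 58 clusters, 43 were named and 4144 cells (6.90%) stayed unnamed. The scoring rule was set after the files were seen, and the markers before. Names are written X-like once and then used without the suffix.

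Counts were summed per library and cell class, and classes with at least 50 cells in a library were tested. The main test was edgeR 4.0.16, quasi-likelihood, over all 6 libraries with 1 mean per group, TMM scaling, edgeR's default filter on low counts and Benjamini-Hochberg adjustment at 0.05 over the genes of each class and comparison. Standard errors (SE) are of the log2 fold change, taken as its size divided by the square root of the edgeR F statistic. CPM are counts scaled to a fixed total of UMIs of that class in that library. For male and female cells CPM were scaled to the sums per library and sex, with TMM factors. DESeq2 1.42.0 was run on the same sums. Gene lists fixed beforehand, 21 in number, were tested with camera in limma 3.58.1 at its preset inter-gene correlation of 0.01, then with the correlation estimated for each list, and with fry. Lists needed at least 5 tested members. Cell shares were compared with a 2-sided exact permutation test over libraries, which with 2 libraries per group cannot go below p = 0.333, and with edgeR on cell counts. The samples, tests, gene lists, markers, cell filter and the rule for named genes were fixed before the data were examined.

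The rule named Hdac5. In keratinocytes it took the 6 genes with the highest and the 6 with the lowest log2 fold change, and in other classes the 4 highest and 4 lowest. These had to have an adjusted p under 0.05, a mean of at least 20 CPM in the higher group and no overlap between the libraries of the groups, and unnamed gene models, mitochondrial, ribosomal, hemoglobin and immunoglobulin genes were left out. Of each list called by camera, or in keratinocytes holding at least 3 members past the test, it took the 2 members with the smallest p.

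RNA that leaks from broken cells is captured in every droplet (free RNA). Its share in a class was estimated as the median ratio between the CPM of markers of other classes in that class and in all cells of the library. It came to 5.80% and 6.08% of keratinocyte UMIs in unwounded skin, 10.7% and 9.68% in control wound edge and 7.89% and 12.1% in cKO wound edge. From it followed the share of each gene's counts that free RNA could supply. Cells were also called male or female, where they had at least 5000 UMIs, from at least 3 UMIs of Xist against 4 Y-linked genes at a ratio of at least 3.

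The tests were run on simulated data in which 200 genes were changed. In keratinocytes, over 18965 genes for the wound comparison and 18968 for the cKO comparison, 62% and 45% of genes changed 2-fold were recovered, and 95% and 92% of those changed 4-fold. In fibroblasts (17426 and 17423 genes) the shares were 76% and 82% at 2-fold and 97% and 98% at 4-fold. Unchanged genes called by mistake were 16 and 8 in keratinocytes and 25 and 27 in fibroblasts, and between 5 and 27 over the classes tested. Next to 200 changed genes, the 25 and 27 in fibroblasts exceeded the share of false calls that an adjusted p threshold of 0.05 allows. So did the 16 in the wound comparison of keratinocytes and the 27 in cKO macrophages or monocytes. The 5 in the wound comparison of endothelial cells did not. The genes called below may therefore hold more false calls than the threshold states. The replicates of a group differed beyond the sampling noise of UMIs, by a chi-square of 45.6, 60.4 and 175 per gene over all cells, so none was a copy of the other. This cannot tell separate animals from repeat captures of the same ones. Alternatives covered scaling, DESeq2, the filter on low counts, doublets, a stricter cell filter, a finer clustering, equal cell numbers, single keratinocyte classes, fewer groups in the fit, a replicate block and leaving out each library. Subtraction of free RNA, a uniform doublet rule, crossed replicate numbers and leaving a library out of the cell shares were chosen after the data were seen. Neutrophils were not tested between wound and unwounded skin, where 4 and 6 cells were found.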

Results

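Gene expression in single cells was measured in unwounded skin and in the wound edge of Hdac5fl/fl mice, and in the wound edge of K14cre;Hdac5fl/fl mice (cKO), with 2 libraries in each group. Hdac5 encodes a class IIa histone deacetylase, a family that represses MEF2 target genes, and the cKO was made to remove it from the epidermis. The totals were 136219512 and 133769166 UMIs in the unwounded libraries, 176425414 and 167223744 in the control wound libraries and 167886452 and 158193132 in the cKO libraries. The median cell kept held 10748.5 and 10552.5 UMIs in unwounded skin, 12714 and 11061 in control wound edge and 11360.5 and 12624.5 in cKO wound edge. The comparisons asked what the wound edge changed in each cell class of control skin, and what the cKO changed at the wound edge. Unwounded cKO skin was not analysed here.

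The targeted gene, Hdac5 (ENSMUSG00000008855, GRCm38 chromosome 11, 102194432 to 102230166, minus strand, protein coding), was detected in keratinocytes of every library. Its level was 61.1 and 56.0 CPM in unwounded skin, 26.5 and 35.3 CPM in control wound edge, and 36.5 and 34.6 CPM in cKO wound edge. Between cKO and control wound edge the log2 fold change was 0.15 (SE 0.14, n = 2 libraries each, edgeR adjusted p = 0.724). Without control wound library 1 it was -0.041, without control wound library 2 it was 0.36, without cKO library 1 it was 0.05 and without cKO library 2 it was 0.23. Free RNA could supply an estimated 9.06% of the Hdac5 counts in cKO keratinocytes and 10.4% in control wound keratinocytes. Within basal keratinocytes Hdac5 was at 26.2 and 26.4 CPM in cKO against 20.4 and 26.7 CPM in control wound edge. Suprabasal keratinocytes held 53.1 and 44.2 CPM against 27.8 and 46.0 CPM. The libraries read the 3' end of the transcript, and the labels do not say which exons were floxed. A tag outside the deleted part counts the remaining transcript and checks nothing, so these values neither show nor exclude a deletion. In fibroblasts, which the K14 promoter does not target, Hdac5 stood at 25.5 and 27.6 CPM in control and 25.9 and 25.8 CPM in cKO wound edge.

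**Figure D1:**
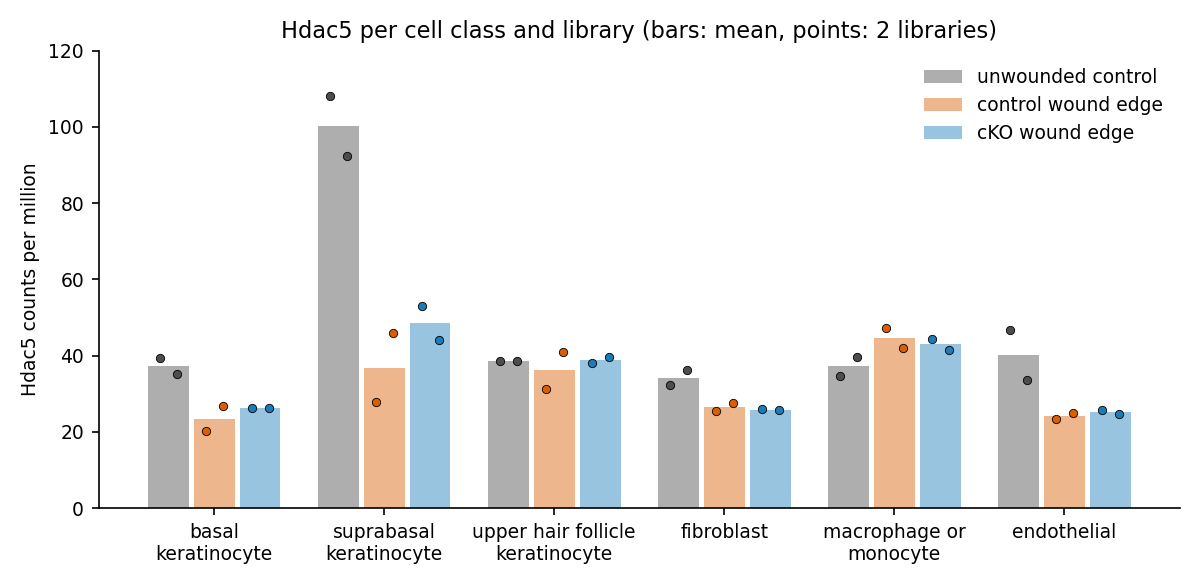
Hdac5 in CPM (vertical axis) for 6 cell classes, with bars at the group mean and points at the 2 libraries of unwounded skin, control wound edge and cKO wound edge. Suprabasal keratinocytes of unwounded skin stand at 108 and 92.5 CPM, above every other bar, and the cKO points lie within or above the control wound points in keratinocytes.

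The wound edge differed from unwounded skin in its cell makeup. Keratinocyte-like cells made up 73.4% and 71.9% of cells in unwounded skin and 42.6% and 43.9% in control wound edge (mean 72.7% ± 1.08 against 43.3% ± 0.944, SD, n = 2). Macrophage- or monocyte-like cells, which clear debris, were at 1.80% and 1.95% against 14.0% and 16.6%. Neutrophil-like cells, early responders to injury, were at 0.0456% and 0.0667% against 2.48% and 2.62%, and endothelial-like cells at 2.80% and 2.59% against 5.78% and 7.07%. Fibroblast-like cells were at 9.61% and 11.1% against 15.5% and 13.8%. Langerhans-like cells, the antigen-presenting cells of the epidermis, were at 2.31% and 2.03% against 0.285% and 0.381%. For each of these 6 classes the exact permutation p was 0.333, the smallest that 2 against 2 libraries allow. With edgeR on cell counts the log2 fold change was -0.75 for keratinocytes (adjusted p = 0.0041), 3.03 for macrophages or monocytes (adjusted p = 5e-12), 5.47 for neutrophils (adjusted p = 5.2e-11), 1.25 for endothelial cells (adjusted p = 1.9e-05), 0.50 for fibroblasts (adjusted p = 0.0475) and -2.70 for Langerhans cells (adjusted p = 5.7e-10). Shares add to a fixed total and depend on how well each cell type came out of the tissue, and the wound libraries also held more unnamed cells, 11.03% and 6.70% against 2.40% and 1.91%.

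**Figure D2:**
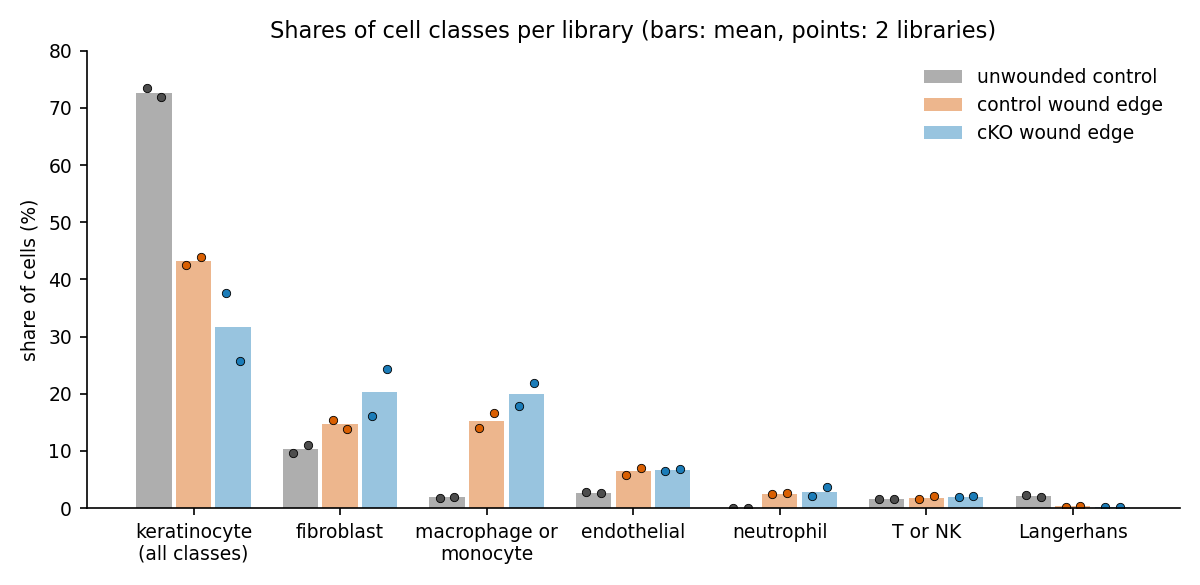
Share of cells in percent (vertical axis) for 7 cell classes, with bars at the group mean and points at the 2 libraries of each group. Keratinocytes fall from 73.4% and 71.9% in unwounded skin to 42.6% and 43.9% in control wound edge and stand at 37.6% and 25.7% in cKO wound edge, while macrophages or monocytes stand at 1.80% and 1.95%, 14.0% and 16.6%, and 18.0% and 21.9%.

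In keratinocytes of the control wound edge, genes of wound-activated epidermis rose and genes of the cornified layer fell. Of 24 wound-activated keratinocyte genes, 16 rose and 1 fell (17 and 1 adjusted over the list alone), with a median log2 fold change of 2.00 (adjusted p = 0.516 with an estimated correlation). Plau and Plaur, the urokinase protease and its receptor, rose by 1.64 (SE 0.13) and 2.94 (SE 0.27). Sprr2i and Sprr2d, which encode small proline-rich proteins of the cell envelope, rose by 8.96 (SE 1.27) and 6.03 (SE 0.85), to 41.4 and 11.7 CPM and to 155 and 31.0 CPM, from 0.00987 and 0.0933 CPM and from 1.14 and 1.74 CPM. In unwounded skin 3 counts would give 0.0296 and 0.0280 CPM, so the size of the Sprr2i change rests on few UMIs there. Of 20 epidermal differentiation genes, 9 fell and 1 rose (10 and 1 adjusted over the list alone), with a median of -1.17 (adjusted p = 0.742 with an estimated correlation). Flg2, a filaggrin family gene, had a log2 fold change of -4.52 (SE 0.71), and Sbsn, which encodes suprabasin, one of -1.91 (SE 0.22, 637 and 665 CPM against 2576 and 2338). The cornified envelope gene Lce1m was at -4.86 (SE 0.73) and the secreted serpin gene Serpina12 at -4.43 (SE 0.28). Tgm3, a transglutaminase of the cornified envelope, went the other way, at 1.61 (SE 0.23). Flg2 and Lce1m are among the leading genes of suprabasal cluster c13, which held 664 and 650 unwounded and 94 and 159 control wound cells. Their fall need not lie within 1 kind of cell. Unnamed clusters are not part of these counts. Among them were c32, 138 cells of control wound library 1 with Hrnr, Flg and Lor among its leading genes, and c31. The latter was led by Sprr2d and Sprr2i and held 59 and 71 control wound cells.

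Of the other keratinocyte lists, glycolysis and interferon response genes mostly rose, while basal layer and junction genes split and no cell cycle gene passed. For comparison, 3118 of all 19279 tested genes rose and 2846 fell. Of 18 glycolysis and hypoxia genes, 13 rose and none fell (13 adjusted over the list alone), among them the hexokinase gene Hk2 at 1.56 (SE 0.11) and the carbonic anhydrase gene Car9 at 1.81 (SE 0.18). Of 19 interferon response genes, 15 rose and 1 fell, the same counts adjusted over the list alone, with Rtp4 at 2.38 (SE 0.20) and Usp18, which dampens interferon signalling, at -1.71 (SE 0.15), and both lists had an adjusted p of 0.516 with an estimated correlation. The 14 basal layer genes split into 1 that rose and 4 that fell (2 and 5 adjusted over the list alone), and the ones that fell held Krt15, a keratin of the basal layer, at -1.81 (SE 0.22). The 16 cell-cell junction genes split into 6 and 4 (6 and 5 adjusted over the list alone), with the desmosomal cadherin Dsc2 at 1.57 (SE 0.26), which missed the threshold without unwounded library 1 (1.64, adjusted p = 0.053) or library 2 (1.49, adjusted p = 0.055). None of 22 cell cycle genes passed with edgeR, although 17 lay above 0, and the median was 0.15.

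Several lists that camera called higher in keratinocytes name genes of other cells, and for these free RNA could supply much of the signal (adjusted p from 0.516 to 0.67 with an estimated correlation). Of 20 cytokine and chemokine genes, 16 rose and 1 fell (17 and 1 adjusted over the list alone), and free RNA could supply a median of 62.4% of their counts at the control wound edge. Cxcl1, a neutrophil attractant, rose by 3.13 (SE 0.19) with 56.6% and Cxcl2 by 5.31 (SE 0.32) with 90.4%. The same median was 96.3% for the extracellular matrix list (14 of 20 rose, 16 adjusted over the list alone, where 1 also fell), 76.0% for the macrophage inflammatory list (13 of 14 rose, also adjusted over the list alone, where 1 fell) and 89.6% for the endothelial list (8 of 16 rose and 2 fell, 11 and 2 adjusted over the list alone). It was 54.5% for the MHC class II list (5 of 7 rose and 1 fell, also adjusted over the list alone) and 67.3% for the macrophage repair list (7 of 14 rose and 1 fell, also adjusted over the list alone).

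Over all genes, edgeR called 3118 higher and 2846 lower of 19279 tested in keratinocytes at the control wound edge (8605 at an unadjusted p under 0.05), and DESeq2 called 3220 and 3261. Camera called 9 lists as higher and 1, epidermal differentiation, as lower. For wound-activated genes the camera adjusted p was 9.8e-06, and the adjusted p was 0.516 with an estimated correlation. The other lists called higher had an adjusted p between 0.516 and 0.67 with an estimated correlation, and epidermal differentiation (camera adjusted p = 0.0019) one of 0.742. The edgeR count was 1693 without unwounded library 1, 2352 without unwounded library 2, 1277 without control wound library 1 and 2716 without control wound library 2, where the lone library left in a group was assumed to vary like the others. Different clusters held most basal and suprabasal cells of unwounded skin (c3, c10 and c13) and of wounds (c2 and c9), so the keratinocyte changes above need not lie within 1 kind of cell.

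**Figure D3:**
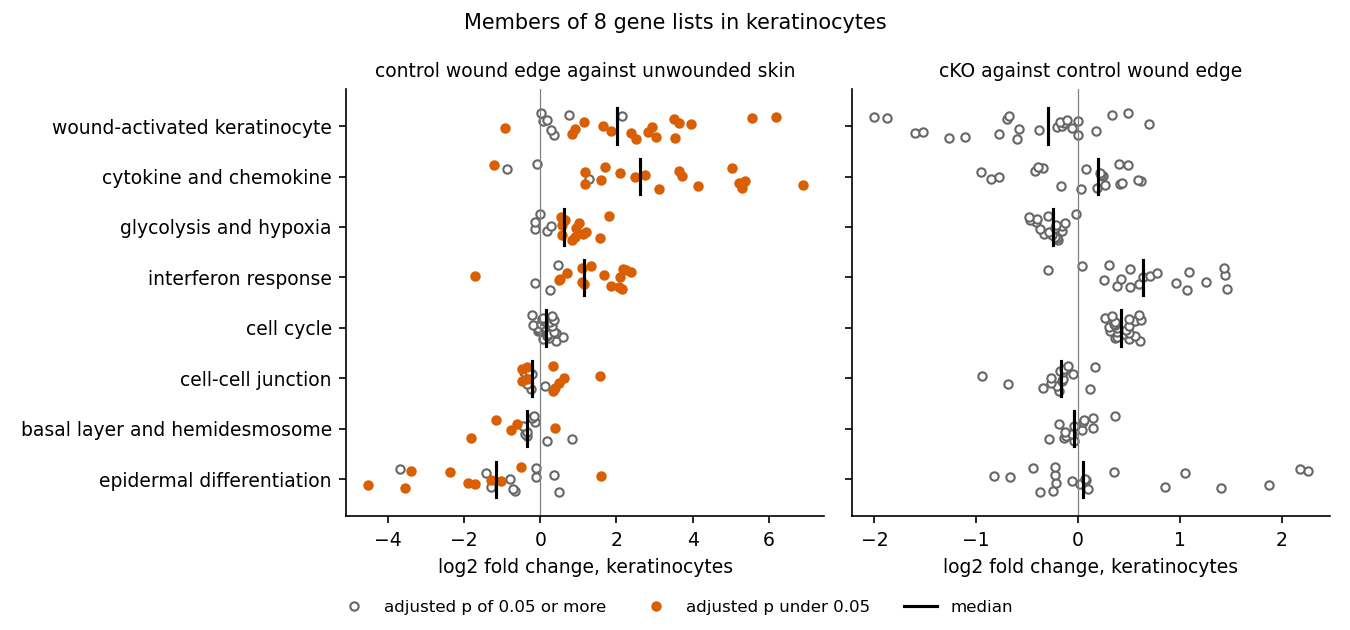
Log2 fold change of each tested member of 8 gene lists in keratinocytes (horizontal axis), for control wound edge against unwounded skin on the left and cKO against control wound edge on the right. Filled points pass the edgeR test at an adjusted p under 0.05, open points do not, and the black bar is the list median, which is 2.00 on the left for wound-activated genes and 0.64 on the right for interferon response genes, where no point is filled.

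Fibroblasts of the control wound edge had higher levels of matrix, chemokine and cell cycle genes than those of unwounded skin (adjusted p = 0.418 with an estimated correlation for each list). Of 20 extracellular matrix genes, 18 rose and none fell (18 adjusted over the list alone), among them the collagen crosslinking enzymes Lox at 2.32 (SE 0.09) and Loxl2 at 1.81 (SE 0.10). Of 20 cytokine and chemokine genes, 19 rose (20 adjusted over the list alone), with the alarmin Il33 at 3.81 (SE 0.21) and Cxcl12 at 1.28 (SE 0.09). Of 22 cell cycle genes, 20 rose (21 adjusted over the list alone), with the cyclin genes Ccna2 at 2.30 (SE 0.14) and Ccnb2 at 2.70 (SE 0.19). Saa3, an acute-phase serum amyloid gene, stood at 3001 and 2994 CPM against 2.18 and 5.45 CPM, a log2 fold change of 9.74 (SE 0.31). Reg3g, an antimicrobial lectin gene, was at 26.5 and 25.7 CPM in control wound fibroblasts with no UMI in either unwounded library, where 3 counts would give 0.385 and 0.309 CPM. Myoc and Inmt fell by 4.35 (SE 0.37) and by 3.96 (SE 0.34).

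In the same fibroblasts, 20 of 24 wound-activated genes rose (21 adjusted over the list alone), but free RNA could supply a median of 100% of their counts (adjusted p = 0.418 with an estimated correlation). Itga5, an integrin of the fibronectin receptor, at 1.97 (SE 0.12), and the growth factor gene Ereg, at 5.49 (SE 0.36), were exceptions with 6.08% and 5.95%. Of 18 glycolysis and hypoxia genes 11 rose and 1 fell (11 and 2 adjusted over the list alone), and of 16 oxidative phosphorylation genes 11 rose (11 adjusted over the list alone), with an adjusted p of 0.577 and 0.418 with an estimated correlation. Of 14 macrophage inflammatory genes, 12 rose (12 adjusted over the list alone), with the prostaglandin synthase Ptgs2 at 3.25 (SE 0.23) and Il6 at 1.67 (SE 0.12), and the adjusted p was 0.51 with an estimated correlation. The MEF2 and class IIa HDAC list went the other way. Of its 12 genes, 7 fell and 2 rose (7 and 2 adjusted over the list alone), with the transcription factors Mef2c at -1.44 (SE 0.15) and Mef2a at -0.91 (SE 0.08), and the adjusted p was 0.545 with an estimated correlation. In all, edgeR called 4110 genes higher and 3509 lower of 17745 (DESeq2 3696 and 3107), and 4698 in all without control wound library 2. Camera called 7 lists higher and the MEF2 list lower (adjusted p = 0.0451), and none of the 8 with an estimated correlation, where the adjusted p ranged from 0.418 to 0.577. Wound fibroblasts lay mostly in clusters c7 and c4, and unwounded fibroblasts in c4, c12 and c20.

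Macrophages or monocytes of the control wound edge had higher inflammatory and glycolysis genes and lower antigen-presentation genes (adjusted p = 0.336 with an estimated correlation for each list). Of 14 macrophage inflammatory genes, 12 rose and none fell (13 adjusted over the list alone), with Tnf, the inflammatory cytokine, at 2.61 (SE 0.15) and Cxcl2 at 1.42 (SE 0.10, 5498 and 5545 CPM against 2290 and 2096). Of 18 glycolysis and hypoxia genes, 12 rose and 1 fell (13 and 1 adjusted over the list alone), with the angiogenic factor Vegfa at 3.93 (SE 0.32). All 7 MHC class II genes fell (7 adjusted over the list alone), with H2-DMb1 at -1.67 (SE 0.14) and Cd74, the invariant chain, at -0.91 (SE 0.10). Of 12 unfolded protein response genes, 6 fell (8 adjusted over the list alone), with the chaperone Hsp90b1 at -1.01 (SE 0.10), and of 19 interferon response genes 4 fell (6 adjusted over the list alone), with Isg15 at -1.19 (SE 0.16), where the lists had an adjusted p of 0.336 and 0.582 with an estimated correlation. Retnla, a marker of alternatively activated macrophages, stood at 1.34 and 6.29 CPM against 2873 and 2434 CPM, a log2 fold change of -9.28 (SE 0.43). Cd226, a receptor of the immunoglobulin family, was at -6.32 (SE 0.39).

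Also in macrophages or monocytes, 10 of 18 cytokine and chemokine genes rose and 1 fell (11 and 1 adjusted over the list alone, adjusted p = 0.336 with an estimated correlation). Lists of keratinocyte and stromal genes that camera also called were extracellular matrix (15 of 20 rose and 1 fell, 16 and 1 adjusted over the list alone), wound-activated keratinocyte (13 of 24 rose, 15 adjusted over the list alone), epidermal differentiation (8 of 19 fell, 8 adjusted over the list alone, where 1 rose) and cell-cell junction (2 of 15 fell and 1 rose, 4 and 1 adjusted over the list alone). Free RNA could supply a median of 100%, 74.8%, 86.3% and 100% of their counts at the wound edge, and their adjusted p was 0.336, 0.336, 0.582 and 0.336 with an estimated correlation. The endothelial list (4 of 16 rose and 1 fell, 6 and 1 adjusted over the list alone, adjusted p = 0.336 with an estimated correlation) had a median of 85.7%. EdgeR called 1229 genes higher and 1036 lower of 14291 (4173 at an unadjusted p under 0.05), and DESeq2 1092 and 1075. The count was 1406 without unwounded library 1, 1358 without unwounded library 2 and 1403 without control wound library 1. Camera called 6 lists higher and 5 lower, and the adjusted p of these 11 ranged from 0.336 to 0.582 with an estimated correlation. The unwounded libraries held 158 and 175 such cells, and cluster c0 held most of the class in every library. The cells compared still differed in kind. A finer clustering put 78 and 72 unwounded cells in a cluster left unnamed, with the macrophage genes Mrc1, Cd163 and Folr2 among its leading genes, and 32 and 35 in its largest macrophage cluster, against 237 and 297 and 973 and 1278 control wound cells, so the changes above need not lie within 1 kind of cell. Retnla is among the leading genes of cluster c19.2, which held 29 and 37 of the unwounded and 8 and 8 of the control wound cells.

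Endothelial cells of the control wound edge were higher in cell cycle genes and lower in interferon response genes (adjusted p = 0.453 with an estimated correlation for both lists). Of 22 cell cycle genes, 19 rose and none fell (19 adjusted over the list alone), with the topoisomerase gene Top2a at 3.58 (SE 0.17) and the cyclin-dependent kinase gene Cdk1 at 3.72 (SE 0.24). Of 19 interferon response genes, 11 fell and 2 rose (12 and 2 adjusted over the list alone), with Rsad2 at -1.26 (SE 0.11). The chemokine gene Cxcl12 was at -1.75 (SE 0.13) and Timp4, an inhibitor of metalloproteinases, at -4.95 (SE 0.26). Chga, a granin gene, was at 30.7 and 36.8 CPM with no UMI in unwounded skin, where 3 counts would give 1.89 and 1.65 CPM. The extracellular matrix list (16 of 20 rose and 1 fell, 18 and 2 adjusted over the list alone) had a median of 72.4% of its counts from free RNA. Free RNA could supply a median of 96.7% for the wound-activated list, 100% for epidermal differentiation, 75.8% for cytokines and 40.8% for the macrophage inflammatory list, which camera also called. The 7 lists called by camera had an adjusted p between 0.453 and 0.52 with an estimated correlation. EdgeR called 2053 genes higher and 1771 lower of 15076 (5745 at an unadjusted p under 0.05), and DESeq2 1912 and 1576. Without unwounded library 1, control wound library 1 or control wound library 2 the count was 2326, 2213 or 2520.

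T or NK cells of the control wound edge were higher in cell cycle genes. Of 22 such genes, 16 rose and none fell (20 adjusted over the list alone, adjusted p = 0.119 with an estimated correlation), with the proliferation marker Mki67 at 2.37 (SE 0.18, 277 and 284 CPM against 52.8 and 52.7). Of 16 interferon response genes, 3 rose and none fell (5 adjusted over the list alone), with Ifi27l2a at 2.25 (SE 0.20), and the list had an adjusted p of 0.268 with an estimated correlation. The chemokine gene Ccl3 was at 3.26 (SE 0.30). Il22, a cytokine that acts on epithelium, was at 519 and 83.3 CPM with no UMI in unwounded skin, where 3 counts would give 3.77 and 1.82 CPM, and it leads cluster c16.1. The classes compared differed in kind. Unwounded T or NK cells lay mostly in cluster c25, which is led by the gamma-delta T cell gene Trdc, and wound cells in the clusters of c16. Keratinocyte genes were high in the unwounded cells, where the free RNA estimate was 9.09% and 37.5%. Its quartiles ran from 5.72% to 29.7% and from 10.3% to 98.9%, too wide to say that these genes lie beyond free RNA. Of 14 basal layer genes 11 fell, and of 14 cell-cell junction genes 10 fell (11 and 13 adjusted over the list alone, adjusted p = 0.443 with an estimated correlation for both). Col17a1, a hemidesmosome collagen, was at 490 and 952 CPM in unwounded against 61.3 and 72.6 CPM in control wound cells, and free RNA could supply 21.8% and 96.1% of these counts. Doublets made up 15.1% of c25 before they were removed. EdgeR called 846 genes higher and 766 lower of 10877 (3266 at an unadjusted p under 0.05), and DESeq2 595 and 546. The count was 1000 without unwounded library 2, 339 without control wound library 1, 221 without control wound library 2 and 1062 without cKO library 2. The immediate early, cytokine, matrix, macrophage inflammatory and endothelial lists, which camera also called, had an adjusted p between 0.407 and 0.608 with an estimated correlation.

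At the cKO wound edge keratinocyte-like cells made up 37.6% and 25.7% of cells, against 42.6% and 43.9% at the control wound edge. The difference was -11.6 percentage points (exact permutation p = 0.333, the smallest possible, and edgeR log2 fold change -0.45, adjusted p = 0.231). It was -17.6 points without cKO library 1 and -5.69 points without cKO library 2. Suprabasal cells were at 7.52% and 3.40% against 10.98% and 10.6%, and basal cells at 14.2% and 6.86% against 14.9% and 17.9%. Macrophages or monocytes were at 18.0% and 21.9% against 14.0% and 16.6% (edgeR adjusted p = 0.306), fibroblasts at 16.1% and 24.4% against 15.5% and 13.8% (adjusted p = 0.231) and neutrophils at 2.04% and 3.66% against 2.48% and 2.62% (adjusted p = 0.844). Langerhans cells had the smallest p, at 0.181% and 0.121% against 0.285% and 0.381% (19 and 11 cells against 31 and 45, edgeR log2 fold change -1.12, unadjusted p = 0.00412, adjusted p = 0.0700).

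In cKO keratinocytes no single gene passed the edgeR test against the control wound edge, while DESeq2 called 68 higher and 129 lower. Camera called the interferon response and cell cycle lists higher (adjusted p = 0.656 with an estimated correlation for both). Of 19 interferon response genes, 18 lay above 0, with a median log2 fold change of 0.64, none passed over all genes and 10 rose adjusted over the list alone. Ifi27l2a was at 138 and 124 CPM against 48.3 and 45.1 CPM (1.43, SE 0.16, edgeR adjusted p = 0.456). Ifi44 was at 4.26 and 3.16 CPM against 1.22 and 1.44 CPM (1.44, SE 0.24, adjusted p = 0.456). Free RNA could supply 23.7% of the Ifi27l2a counts in cKO and 36.4% in control. The list's camera adjusted p was 1.3e-10. Of 22 cell cycle genes, 22 lay above 0, with a median of 0.42, and none passed over all genes or adjusted over the list alone. Mki67 was at 129 and 135 CPM against 95.8 and 70.5 CPM. The list's camera adjusted p was 1.1e-09. Its median was 0.37 within basal keratinocytes, and 0.10 within suprabasal and within upper hair follicle keratinocytes. The basal class includes cluster c11, with Top2a and Mki67 among its leading genes. It held 475 of 1489 and 193 of 622 basal cells in cKO, against 493 of 1626 and 357 of 2120 in control wound edge. The basal rise therefore need not lie within 1 kind of cell.

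Camera called 6 lists lower in cKO keratinocytes, glycolysis and hypoxia, junction, immediate early and heat shock, p53 targets and blood (adjusted p = 0.656 with an estimated correlation for each) and wound-activated (adjusted p = 0.67 with an estimated correlation). The pooled keratinocytes differed in makeup. Suprabasal cells were 788 of 3935 and 308 of 2331 keratinocytes in cKO, against 1195 of 4636 and 1254 of 5192 in control wound edge. The list changes in this paragraph therefore need not lie within 1 kind of cell. None of the 18 glycolysis and hypoxia genes lay above 0, the median was -0.25, and 1 fell adjusted over the list alone. Ndrg1, a hypoxia response gene, was at 120 and 116 CPM against 151 and 168 CPM. The cell-cell junction list had a median of -0.16, and 4 of 16 genes fell adjusted over the list alone. Ocln, which encodes occludin of tight junctions, was at 78.8 and 85.8 CPM against 99.0 and 102 CPM. The wound-activated list had a median of -0.30 over 24 genes, none of which passed adjusted over the list alone. Control wound library 1 stood apart for some of them, with Krt16 at 942 and 767 CPM in cKO against 2365 and 1183 CPM, and in suprabasal cells at 2988 and 3164 CPM against 6405 and 3182 CPM. Krt6b was at 976 and 1183 CPM against 2402 and 1029 CPM in suprabasal cells. These values were looked up after the results were seen. Sprr1a was at 109 and 102 CPM against 207 and 141 CPM, and the growth factor gene Hbegf at 284 and 286 CPM against 379 and 336 CPM. The immediate early and heat shock list had a median of -0.17 (5 of 18 fell adjusted over the list alone), with the chaperone genes Dnajb1 at 321 and 359 CPM against 430 and 506 CPM and Hspa1b at 255 and 226 CPM against 315 and 332 CPM. The p53 target list had a median of -0.10 (1 of 13 fell adjusted over the list alone), with the cell cycle inhibitor gene Cdkn1a at 181 and 173 CPM against 218 and 242 CPM. The MEF2 and class IIa HDAC list, which holds genes that Hdac5 and its relatives act on or encode, had a median of 0.06 over 12 genes, and the list of other histone deacetylases one of 0.12 over 11 genes, with none past the test over all genes or adjusted over the list alone in either (camera adjusted p = 0.961 and 0.268).

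Camera called 6 lists higher and 6 lower in cKO keratinocytes, none of them with an estimated correlation (adjusted p from 0.656 to 0.721), and 6 in all without cKO library 2. The higher ones also held the matrix, macrophage repair, endothelial and muscle lists. Free RNA could supply a median of 91.1%, 60.9%, 86.8% and 43.6% of their counts in cKO, and their adjusted p was 0.721, 0.656, 0.721 and 0.656 with an estimated correlation. The sixth lower list was blood, with a median of -2.37 (adjusted p = 0.656 with an estimated correlation) and Hbb-bs at 0.425 and 0.205 CPM against 3.28 and 10.2 CPM. Hbb-bs is a hemoglobin gene, and free RNA as the source of its counts is left open. EdgeR called 0 of 19279 genes (1890 at an unadjusted p under 0.05), and DESeq2 called 68 higher and 129 lower. By class, edgeR called Ifi27l2a alone in basal keratinocytes (1.72, adjusted p = 0.0406) and in upper hair follicle keratinocytes (1.60, adjusted p = 3.2e-05), and Serpina12 alone in suprabasal keratinocytes (2.41, adjusted p = 0.0179), where the unadjusted counts were 1691, 1294 and 1275. DESeq2 called 75, 37 and 39 genes there. These 3 calls were looked up after their values were seen.

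**Figure D4:**
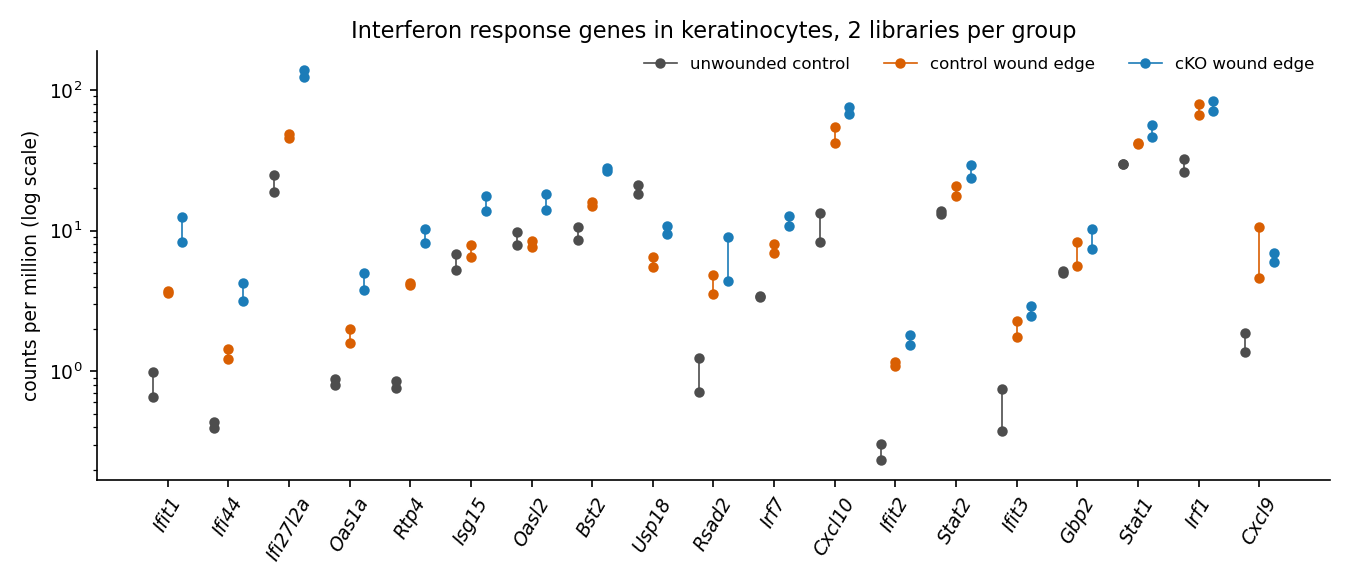
CPM of interferon response genes in keratinocytes on a log scale (vertical axis), with a point for each of the 2 libraries of unwounded skin, control wound edge and cKO wound edge. Ifi27l2a stands at 138 and 124 CPM in cKO against 48.3 and 45.1 CPM in control wound edge, and 18 of 19 members have a log2 fold change above 0, though none passes the edgeR test over all genes.

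In cKO fibroblasts edgeR called 0 of 17745 genes (1055 at an unadjusted p under 0.05) and DESeq2 called 27 higher and 55 lower. The cell-cell junction list had a median of -0.65 with 0 of 16 genes above 0 and 11 that fell adjusted over the list alone, but free RNA could supply a median of 100% of its counts (adjusted p = 0.233 with an estimated correlation). Cdh1, the epithelial cadherin, was at 27.6 and 27.03 CPM against 42.7 and 51.7 CPM, and Krt14 at 510 and 389 CPM against 835 and 732 CPM. The epidermal differentiation, basal layer and wound-activated lists were also lower (medians -0.61, -0.45 and -0.40, with 7, 7 and 4 genes that fell adjusted over the list alone), with 100%, 96.7% and 82.9% from free RNA (adjusted p = 0.404, 0.352 and 0.352 with an estimated correlation). Of the remaining lists camera called, cell cycle (median 0.20, 22 of 22 genes above 0), MHC class II (0.28) and oxidative phosphorylation (0.08) were higher, and immediate early and heat shock (-0.31, 1 gene fell adjusted over the list alone) and p53 targets (-0.12) lower, with an adjusted p of 0.352 or 0.358 with an estimated correlation. Dnajb1 was at 150 and 137 CPM against 230 and 242 CPM. The blood list had a median of -1.44 and the muscle list one of 1.31, where 2 genes rose adjusted over the list alone (adjusted p = 0.352 and 0.404 with an estimated correlation). Free RNA as the source of the counts of both lists is left open. Camera called 11 lists in all, and 6 without control wound library 1.

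In cKO macrophages or monocytes edgeR called 0 of 14291 genes (600 at an unadjusted p under 0.05) and DESeq2 1 higher and 1 lower. EdgeR called 165 genes without cKO library 1, 1 without control wound library 2 and 4 without cKO library 2. The macrophage repair list had a median of 0.14 (2 of 14 genes rose and 1 fell adjusted over the list alone, adjusted p = 0.371 with an estimated correlation). Retnla was at 10.96 and 20.5 CPM against 1.34 and 6.29 CPM (1.98, SE 0.43, adjusted p = 0.864, and 2.34 with an adjusted p of 0.0018 without cKO library 1). Cd163, a scavenger receptor, was at 59.7 and 40.8 CPM against 29.2 and 37.3 CPM. The matrix and endothelial lists were higher (medians 0.53 and 0.36), and the wound-activated, epidermal differentiation and cell-cell junction lists lower (-0.23, -0.26 and -0.19, with 5, 2 and 2 genes that fell adjusted over the list alone). For these 5 lists free RNA could supply a median of 100%, 86.2%, 69.8%, 96.0% and 99.6%, and the adjusted p was 0.371 or 0.759 with an estimated correlation. The glycolysis list was at -0.11 and the immediate early and heat shock list at -0.13 (1 gene fell adjusted over the list alone), with an adjusted p of 0.371 and 0.759 with an estimated correlation. Camera called 8 lists in all, and 3 without cKO library 2.

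Neutrophils of the cKO wound edge had lower levels of 4 granule genes, the only genes edgeR called of 6617 tested (289 at an unadjusted p under 0.05, and 1 by DESeq2). Few cells held their UMIs, as 2 and 3 control cells held 70.5% and 93.5% of the UMIs of the 4 genes, and 29 of 270 and 31 of 310 control cells held any. Camp, an antimicrobial peptide precursor, was at 25.9 and 0 CPM against 435 and 393 CPM, a log2 fold change of -5.40 (SE 0.70, adjusted p = 0.0284). In the cKO library without a Camp UMI, 3 counts would give 2.55 CPM. Ltf, which encodes lactoferrin, was at -4.22 (SE 0.46), Ngp at -3.78 (SE 0.44) and the chitinase-like Chil3 at -4.61 (SE 0.53), each with an adjusted p of 0.0151. The cytokine and chemokine list had a median of 0.67 with 14 of 16 genes above 0 and 2 that rose adjusted over the list alone, and the matrix list one of 0.69 with a median of 100% from free RNA (adjusted p = 0.61 with an estimated correlation for both). Camera also called the unfolded protein response, macrophage inflammatory and endothelial lists higher (medians 0.31, 0.26 and 0.36) and the interferon response list lower (-0.15), with an adjusted p between 0.61 and 0.887 with an estimated correlation. In the same cells 7 mitochondrial genes, which can mark cell or RNA quality, lay between -0.79 (mt-Co3) and -0.64 (mt-Nd1), at unadjusted p from 0.000745 to 0.00588 and without passing the test, which was looked up after the results were seen. The class held 270 and 310 cells in control and 214 and 332 in cKO. EdgeR called 12, 19, 85 and 182 genes without control wound library 1, control wound library 2, cKO library 1 and cKO library 2. The count was 0 without a filter on low counts and 0 with free RNA subtracted.

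In cKO endothelial cells edgeR called 0 of 15076 genes (494 at an unadjusted p under 0.05, and 1 higher and 2 lower by DESeq2). The count was 10 without control wound library 2, 2 without cKO library 1 and 2 without cKO library 2. The cell-cell junction list (median -0.51, adjusted p = 0.199 with an estimated correlation) and the wound-activated list (median -0.35, adjusted p = 0.748 with an estimated correlation) were lower, with 4 and 7 genes that fell adjusted over the list alone. Free RNA could supply a median of 100% of the counts of both. The immediate early and heat shock list had a median of -0.19 with 2 of 18 genes above 0 (adjusted p = 0.567 with an estimated correlation).

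In cKO T or NK cells edgeR called 0 of 10877 genes (362 at an unadjusted p under 0.05, and 12 lower by DESeq2). It called 19 without unwounded library 1, 16 without unwounded library 2 and 3 without control wound library 1. The epidermal differentiation list had a median of -1.93, and 7 of 9 genes fell adjusted over the list alone (adjusted p = 0.612 with an estimated correlation). Sbsn was at 32.9 and 41.9 CPM against 116 and 173 CPM (adjusted p = 0.12), with 98.8% and 58.4% from free RNA. Camera also called the immediate early (-0.31) and junction (-0.35) lists lower and the macrophage repair (0.66) and endothelial (0.65) lists higher, with an adjusted p between 0.612 and 0.779 with an estimated correlation.

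Male and female cells were present in every library, as told from Xist and 4 Y-linked genes, so sex was compared within libraries. Of the keratinocytes that could be called, 23.6% and 30.6% were male in unwounded skin, 40.3% and 32.6% in control wound edge and 48.3% and 39.4% in cKO wound edge. In unwounded skin male keratinocytes held more of the wound keratin gene Krt6b than female ones (43.7 and 190 CPM against 1.59 and 9.43 CPM), while the control wound libraries held 982 and 423 CPM against 656 and 300.4 CPM. Male fibroblasts of unwounded skin held more Col1a1, a fibrillar collagen gene (15911 and 16306 CPM against 3541 and 3536 CPM). Tested as an interaction with edgeR, the change from unwounded skin to control wound edge differed between male and female cells for 10 of 17457 genes in keratinocytes (814 at an unadjusted p under 0.05) and 13 of 14404 in fibroblasts (2090). The change from control to cKO wound edge differed for 0 genes in both classes (878 and 270 at an unadjusted p under 0.05, DESeq2 not run). Camera called 6 lists for the wound and 2 for the cKO interaction in keratinocytes and 10 and 5 in fibroblasts, and 0 in each with an estimated correlation. In keratinocytes the interferon response list had a median log2 fold change of 0.91 in male and 0.39 in female cells between cKO and control wound edge, a median difference of 0.60 (camera adjusted p = 7.7e-06, and adjusted p = 0.834 with an estimated correlation).

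**Figure D5:**
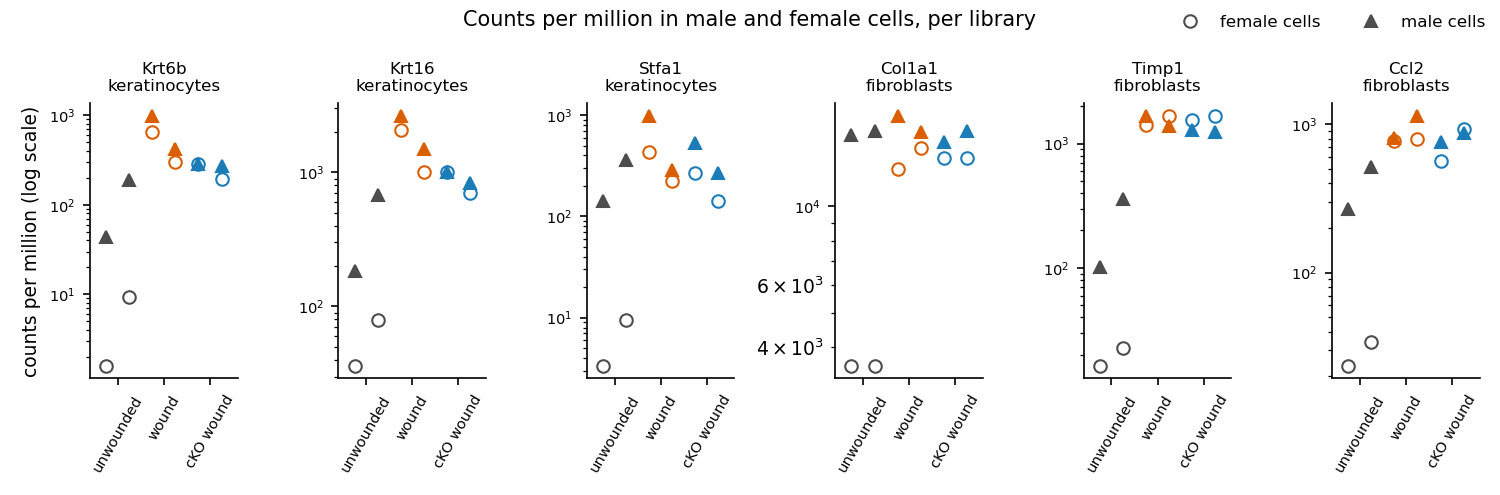
CPM on a log scale (vertical axis) of 3 genes in keratinocytes and 3 in fibroblasts, with open circles for female and triangles for male cells of each of the 6 libraries. In unwounded skin male cells lie above female cells for each of the 6 genes, for example 43.7 and 190 CPM against 1.59 and 9.43 CPM for Krt6b, and in the wound libraries the symbols lie closer together.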

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

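Each library held male and female cells, and the genes below were singled out because their change from unwounded skin to control wound edge differed between the male and female cells of the same libraries (edgeR interaction test). This split was not part of the plan and was made after Xist and Y-linked genes were seen together in every library. The tests of separate animals, of wound cells in unwounded skin, of the wound-activated list without each unwounded library, of the keratinocyte classes for the interferon list and of the spread of granule UMIs over the cells that hold one were chosen after the results were seen.

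In keratinocytes the male minus female difference in log2 fold change was -3.98 for Krt6b, -2.25 for Krt16, -4.56 for Stfa1, -4.71 for Cstdc5, -3.59 for Cstdc6, -3.13 for Il24, -4.10 for Nppb, -3.28 for Gsta4, -2.80 for 2610528A11Rik and 2.14 for Pinlyp (edgeR adjusted p from 0.00211 to 0.0471). Krt6b and Krt16 encode keratins of activated epidermis, and Stfa1, Cstdc5 and Cstdc6 belong to the stefin family of protease inhibitors. In unwounded skin male keratinocytes already held more Krt16 (182 and 675 CPM against 36.0 and 79.4 in female cells) and Stfa1 (142 and 362 CPM against 3.34 and 9.50).

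In fibroblasts the difference was -1.87 for Col1a1, -1.74 for Col3a1, -1.79 for Sparc, -3.87 for Cthrc1, -3.42 for Timp1, -1.94 for Srpx2, -3.44 for Ccl2, -2.16 for Cxcl1, -3.03 for Cxcl2, -7.29 for Il1rl1, -3.36 for Mecom, -4.27 for Sntg1 and -2.74 for Gm17268 (edgeR adjusted p from 0.0221 to 0.0392). Col1a1, Col3a1, Sparc and Cthrc1 are matrix genes, and Ccl2, Cxcl1 and Cxcl2 encode chemokines. In unwounded skin male fibroblasts held 103 and 359 CPM of Timp1 against 16.3 and 22.5 in female fibroblasts, and 269 and 516 CPM of Ccl2 against 23.5 and 34.0.

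Tested apart, edgeR called 2125 genes higher and 1720 lower at the control wound edge in male keratinocytes and 2072 and 1681 in female ones, and 791 and 620 in male fibroblasts and 3737 and 2956 in female ones (for the difference, 814 of 17457 and 2090 of 14404 genes had an unadjusted p under 0.05). Male fibroblasts numbered 94 and 103 in unwounded skin and 208 and 259 in control wound edge, against 306 and 350 and 826 and 704 female ones. Fewer genes were also tested in them, 13124 against 16616, so the gap in fibroblast counts cannot be read as a weaker response. The wound-activated list had a median difference of -0.53, but -0.19 without unwounded library 2 and -1.37 without library 1. The mix of keratinocyte classes could give such a difference, yet within basal keratinocytes it was -1.63 (-0.93 and -1.83 without unwounded libraries 1 and 2), and a rule that called each cell by whichever marker had more UMIs gave -0.64 (-1.40 and -0.31). The basal class still pools clusters of unwounded skin (c3) and of wounds (c2). The unwounded libraries held 29 and 106 cells of c2, and 29 and 104 of the suprabasal wound cluster c9. A mix of cell states within a class is therefore not excluded, and how male and female cells divide between these clusters was not tested. Cells from wounds in the unwounded libraries are left open, since 5.99% and 25.7% of male cells would bring their Krt6b, with 0.0361% and 0.197% neutrophils, and 0.0456% and 0.0667% were seen. Male and female cells come from different animals, so sex, animal and piece of skin cannot be told apart, and irritated skin of the male donors is a hypothesis that was not tested.

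The interferon response list was higher in cKO keratinocytes by camera (median 0.64, adjusted p = 0.656 with an estimated correlation). RNA from other cells at the estimated share does not account for it, as the median was 1.17 after that share was subtracted. The quartiles of the estimate were 6.73% to 10.2% and 9.23% to 15.3% in the 2 cKO libraries, and a larger share was not tested. A changed mix of basal, suprabasal and upper hair follicle keratinocytes alone does not account for it, as the medians within them were 1.17, 0.51 and 0.81. The bulge, matrix and sebaceous classes were not tested apart. Basal and suprabasal cells each pool several clusters, so a mix of cell states within a class is not excluded. A changed mix of male and female cells does not account for it either, as the list was higher within each, by 0.39 in female and 0.91 in male cells. The median difference between male and female cells was 0.60 (camera adjusted p = 7.7e-06, and adjusted p = 0.834 with an estimated correlation). The hypothesis that the cKO raises interferon genes in keratinocytes is left open, because the animals of the 2 libraries per group may differ in infection or wound state, which was not tested.

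The granule genes that were lower in cKO neutrophils were seen in few cells. At least 1 UMI of Camp, Chil3, Ltf or Ngp was seen in 29 and 31 of 270 and 310 control wound cells, against 9 and 16 of 214 and 332 cKO cells, and at least 10 were seen in 4 and 4 against 1 and 0. In the control wounds 1 cell held 475 of 1151 such UMIs in library 1 and 412 of 981 in library 2, and the highest cells, under 10% of those with a UMI, held 70.5% and 93.5%. The planned measure decides nothing, as at least 99.7% of the control UMIs lay in under 10% of all these cells, where an even spread over the cells with a UMI would already give 89.7% and 96.8%. The highest cells, 2 in control wound library 1 and 3 in library 2, thus held most of these UMIs, so the summed control levels rest on few cells. Cells with at least 1 such UMI were also fewer in cKO, and whether a difference remains without the highest cells was not tested. What kind of cell these are was not tested, and no biological explanation was tested.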

How the results depend on the processing

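All 24 alternatives to the settings used were run. Free RNA subtraction, the uniform doublet rule, crossed replicate numbers, keratinocytes without matrix and sebaceous clusters, list counts within basal or suprabasal cells, and leaving a library out of the cell shares were chosen after the results were seen. For the named genes, 2404 pairs of gene and setting kept their direction and side of the threshold, 52 gained a call, 27 lost one and 9 turned direction or went to 0 without passing the test (among them Krt14 in cKO fibroblasts, from -0.79 to 0.35 with free RNA subtracted), and with a library left out 1301 kept it, 25 gained, 50 lost and 1 moved. The cause of the changes below was not tested, except that fewer libraries leave fewer degrees of freedom.

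With an estimated correlation the count of gene lists called was 0 in both comparisons of keratinocytes, fibroblasts and macrophages or monocytes. With fry it was 0 in the 3 cKO comparisons, and 13 against 8 in the wound comparison of fibroblasts. With DESeq2 the genes called in cKO were 197 against 0 in keratinocytes, 82 against 0 in fibroblasts, 2 against 0 in macrophages, 1 against 4 in neutrophils, 3 against 0 in endothelial cells and 12 against 0 in T or NK cells. Without a filter on low counts they were 70 in fibroblasts, 148 in macrophages, 0 in neutrophils, 120 in endothelial cells and 117 in T or NK cells, and 2627 against 1612 for the wound in T or NK cells. In basal keratinocytes alone 1 gene and 5 lists were called in cKO, against 0 and 12, and in suprabasal keratinocytes alone 1 gene.

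With doublets kept the genes called were 2 in cKO neutrophils, 3 in cKO endothelial cells, 4 in cKO T or NK cells and 2901 for the wound in T or NK cells, and with the uniform doublet rule 18 in cKO T or NK cells. With free RNA subtracted the lists called were 6 against 11 in cKO fibroblasts, 7 against 11 in wound macrophages and 2 against 8 in cKO macrophages, and 0 genes were called in cKO neutrophils. The keratinocyte share differed by -27.8 points between wound and unwounded skin under the stricter cell filter, against -29.4, and edgeR on cell counts gave -0.75.

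Leaving out each library in turn, the genes called in the wound comparison ranged from 1277 to 6989 in keratinocytes (1693, 2352 and 2716 without the unwounded libraries or control wound library 2), 4698 to 7577 in fibroblasts, 1358 to 2528 in macrophages (1406 and 1403), 2213 to 3933 in endothelial cells (2326 and 2520) and 221 to 2381 in T or NK cells (1000, 339 and 1062). The lists ranged from 10 to 13 in keratinocytes, 7 to 9 in fibroblasts and 10 to 12 in macrophages. In cKO the genes ranged from 0 to 0 in keratinocytes and in fibroblasts, 0 to 165 in macrophages (1 and 4), 12 to 182 in neutrophils (19 and 85), 0 to 10 in endothelial cells (2 and 2) and 0 to 19 in T or NK cells (16 and 3). The lists ranged from 6 to 14 in keratinocytes, 6 to 14 in fibroblasts and 3 to 9 in macrophages, and Hdac5 in keratinocytes from -0.041 to 0.36. The keratinocyte share ranged from -30.2 to -28.6 points for the wound and from -17.6 to -5.69 for cKO.

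The labels give the groups the same replicate numbers without saying that they pair animals. In keratinocytes the difference between replicates 1 and 2 correlated at 0.258 between unwounded and control wound libraries, -0.402 between unwounded and cKO and -0.26 between control wound and cKO. In the same order it was 0.0741, -0.000906 and 0.0273 in fibroblasts, and -0.0233, 0.0588 and -0.226 in macrophages or monocytes. With 2 replicates per group these correlations cannot decide whether the numbers pair animals. With a replicate block the genes called were 4681 for the wound and 0 for cKO in keratinocytes, with Hdac5 at 0.16, 7362 and 0 in fibroblasts, 2151 and 0 in macrophages, 6 in cKO neutrophils, 3505 and 0 in endothelial cells, and 1720 and 5 in T or NK cells, where cKO had 0 without it. With the cKO numbers crossed they were 6452 and 0, 7210 and 0, 2283 and 0, 4, 3981 and 1, and 1018 and 0.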

Other observations

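The wound edge held a cluster that matched none of the cell classes looked for. It held 295 cells, doublets included, and was led by Mmp9, Acp5, Atp6v0d2, Ctsk, St18 and Jdp2, and Acp5, Ctsk and Atp6v0d2 are known from osteoclasts, which resorb bone. Without doublets it held 0 and 0 cells in unwounded skin, 79 and 87 in control wound edge and 43 and 81 in cKO wound edge. A smaller unnamed cluster, led by Mmp9, Timp1 and Acp5 and also holding Ctsk among its leading genes, had 0 and 0, 9 and 0, and 50 and 1 cells in the same libraries. Another unnamed cluster, of 232 cells led by the small proline-rich genes Sprr2d, Sprr2i and Sprr1b, held 3 and 1 cells in unwounded skin, 59 and 71 in control and 60 and 38 in cKO wound edge.

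Some resident cell types were a smaller share of control wound edge than of unwounded skin. Lymphatic endothelial cells were at 0.662% and 0.381% against 1.55% and 1.61% (edgeR on cell counts, log2 fold change -1.61, adjusted p = 8.3e-06), and melanocytes, the pigment cells, at 0.331% and 0.372% against 0.923% and 0.834% (-1.32, adjusted p = 0.00013). Dendritic cells went the other way, at 0.836% and 1.015% against 0.376% and 0.378% (edgeR on cell counts, log2 fold change 1.29, adjusted p = 0.00021). Hair matrix or inner root sheath keratinocytes differed within groups, at 4.66% and 0.622% in unwounded skin, 1.14% and 0.152% in control wound edge and 0.229% and 2.32% in cKO wound edge.

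Pericytes or smooth muscle cells, which wrap small vessels, had higher cell cycle genes at the control wound edge. Of 22 such genes, 21 rose (22 adjusted over the list alone), with a median of 3.94 (adjusted p = 0.276 with an estimated correlation). The cells compared differed in kind, as cluster c14, led by the smooth muscle gene Myh11, held 142 and 223 unwounded and 201 and 218 control wound cells, and cluster c18, led by the pericyte gene Rgs5, held 33 and 34 and 164 and 201. EdgeR called 1845 genes higher and 1412 lower of 13768 in this class for the wound and 0 for cKO (606 at an unadjusted p under 0.05, and 8 by DESeq2). In bulge or outer root sheath keratinocytes 12 of 22 cell cycle genes rose at the wound edge and none fell (22 adjusted over the list alone), with an adjusted p of 0.357 with an estimated correlation.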
